A study of Mus musculus with 4 samples.

How the data were processed

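Total RNA from 4 samples of 46C mouse embryonic stem cells, 2 labelled CHIR and 2 labelled CHIR plus Spautin-1, was extracted with Trizol, and libraries were made from it by BGI protocols on an MGI platform, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2 and the mouse genome build mm10. The counting, annotation, library normalization, low-count filter and test behind the comparison are not given in the sources used here. Strand use and the handling of reads shared by gene copies are likewise not given in the sources used here, so values of near-identical copies are uncertain.

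The values used are the log2 fold changes of CHIR plus Spautin-1 over CHIR as the authors deposited them, per the file headers. The Q values, p-values adjusted by the authors over an unstated number of genes, come from the same table, per the file headers. It lists 5021 genes by Entrez number and symbol, 5008 of them typed as mRNA, and every Q value in the authors' deposited table is under 0.05. Rows of genes past the threshold only were used; totals, group levels, values per library and other genes were not analysed here. The depth per sample is therefore unknown, and no standard error or replicate spread can be given. The design fixed before the data were examined named tests for counts or normalized values per library, with the authors' own values to be used where a table holds only those; that last case applied, and no test across libraries was run. P-values across the 4 libraries rest on the authors' Q values. As the test behind them is not given, whether they take in the spread between the libraries is unknown. No label says that the libraries came from separate cultures, so any such spread may be technical.

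Genes were counted as changed at the authors' Q value under 0.05, and the share higher was given an exact (Clopper-Pearson) 95% binomial interval. For 34 gene lists fixed before the data were examined, members in the table were counted as higher or lower and compared with the rest of the table by a two-sided Fisher's exact test. The Benjamini-Hochberg adjustment ran over the 33 lists with a listed member. A list was called at an adjusted p under 0.05. This is a test of direction among listed genes; enrichment was not tested, because the genes tested by the authors are not known, and a count adjusted over the list alone was not possible from Q values. An estimated correlation within lists needs values per library and was not possible either. The lists cover naive, core and formative or primed pluripotency, the 2-cell-like state, Wnt, ERK, STAT3, BMP and SMAD, p53 and ATF4 targets, endoplasmic reticulum stress, heat shock, NRF2, autophagy, lysosome, genes tied to the reported targets of Spautin-1, cholesterol, glycolysis and hypoxia, respiratory chain genes of the nucleus and of mitochondrial DNA, cell cycle phases, histones, ribosomal proteins, immediate early genes, YAP and actin, interferon, imprinted genes, and markers of feeder fibroblasts, endoderm, mesoderm, neural, trophectoderm and germline cells.

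The rule for named genes, fixed before the data were examined, took the 12 largest rises and 12 largest falls, up to 4 members of each list with the largest absolute log2 fold change, and 11 genes fixed by name (Usp10, Usp13, Becn1, Trp53, Axin2, Nanog, Pou5f1, Sox2, Klf4, Esrrb, Tfcp2l1). Its condition on the level in the higher group could not be applied, as no levels were there. Genes named beyond the rule, further list members and the 12 smallest Q values among them, were chosen after their values were seen.

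Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly behind mm10, matched on Entrez number for 4999 of the 5021 genes. Transcript length and GC content came from the longest GENCODE M21 transcript of each gene for 4969 genes (99.0%). Each list was also compared with 10000 random draws of other listed genes of the same number, matched on 10 classes of GC content and 3 of length; the two-sided permutation p is 2 times the smaller share of draws at or beyond the list's share on either side. Symbol families of at least 10 listed genes, chromosomes and a pair of further gene lists were examined after the first results were seen. Alternatives were stricter Q values, an absolute log2 fold change of at least 1, a subtraction of 0.1 or 0.2 from every log2 fold change, the matched draws, and leaving out genes held by more than 1 list or Zfp genes.

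The list tests were tested on simulated data with the table's 5021 genes. Fisher's exact test called 6.0% of 200 random sets of 30 genes and all of 200 sets with 90% higher. Of 200 sets of 60 genes low in GC with no other effect, Fisher's exact test called 80.0% and the matched draws 1.5%. With the share higher lowered by 25 points, the matched draws called all 200. Direction was simulated from the same GC classes that the draws match on, so a bias within a class could not show. Here the draws called only shares below their lowest 2.5%, whereas the list calls were two-sided and adjusted, and Fisher's exact test was two-sided. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.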

Results

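RNA was sequenced from 46C cells, a mouse embryonic stem cell line that carries a fluorescent reporter at the neural gene Sox1. The cells were kept in medium with serum and treated for 24 h with 3 µM CHIR, or with 3 µM CHIR together with 8 µM Spautin-1. CHIR is the short name of an inhibitor of the kinase GSK3, which stabilises beta-catenin and helps to keep mouse embryonic stem cells undifferentiated. Spautin-1 is a small molecule known as an inhibitor of autophagy that acts on the deubiquitinases USP10 and USP13. There were 2 libraries per group, 4 in all, and the labels do not say whether they came from separate cultures. Their differences are known here from the authors' deposited table of CHIR plus Spautin-1 over CHIR, which lists 5021 genes, all with a Q value under 0.05. That table gives 1 log2 fold change and 1 Q value per gene, with no level in either group, no value per library and no standard error. The depth is therefore unknown. Whether the spread between replicates enters the authors' Q values is not known either, as their test is not given. A gene outside the table either missed the threshold or was not tested, and these cases cannot be separated. Direction follows the table's own header, a positive log2 fold change meaning higher with Spautin-1, and no levels were there to check it against. "Rose" and "fell" below refer to genes in that table.

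The comparison asks what Spautin-1 added to CHIR over 24 h. Of 18 listed genes of the formative and primed states, 16 fell in the authors' deposited table, among them Otx2, Zic2, Fgf5 and Dnmt3b. Of 20 listed naive pluripotency genes, 16 rose in the authors' deposited table, with Tbx3, Klf4, Prdm14 and Tfcp2l1 the farthest up, and 4 fell. The call for the naive list only just passed (Fisher's exact adjusted p = 0.049) and ended against genes matched on GC content and length (adjusted permutation p = 0.128). All listed lysosomal genes and all listed genes of cholesterol synthesis and uptake rose, with median rises of 1.71-fold and 1.72-fold in the authors' deposited table. Genes of glycolysis and the hypoxia response fell more often than they rose, as did genes of the G2 and M phases of the cell cycle, the latter without passing against matched genes (adjusted permutation p = 0.0669). Of all genes in the authors' deposited table, 2625 were higher and 2396 lower with Spautin-1, so that 52.3% were higher (exact 95% binomial interval 50.9 to 53.7%, which covers counting over genes only). Among the 1020 genes with an absolute log2 fold change of at least 1 in the authors' deposited table, the balance was the other way, with 428 higher and 592 lower (42.0% higher, exact 95% interval 38.9 to 45.1%). Changes were mostly small: the median absolute log2 fold change in the authors' deposited table was 0.55, with a median of 0.50 among genes that rose and -0.62 among genes that fell.

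**Figure D1:**
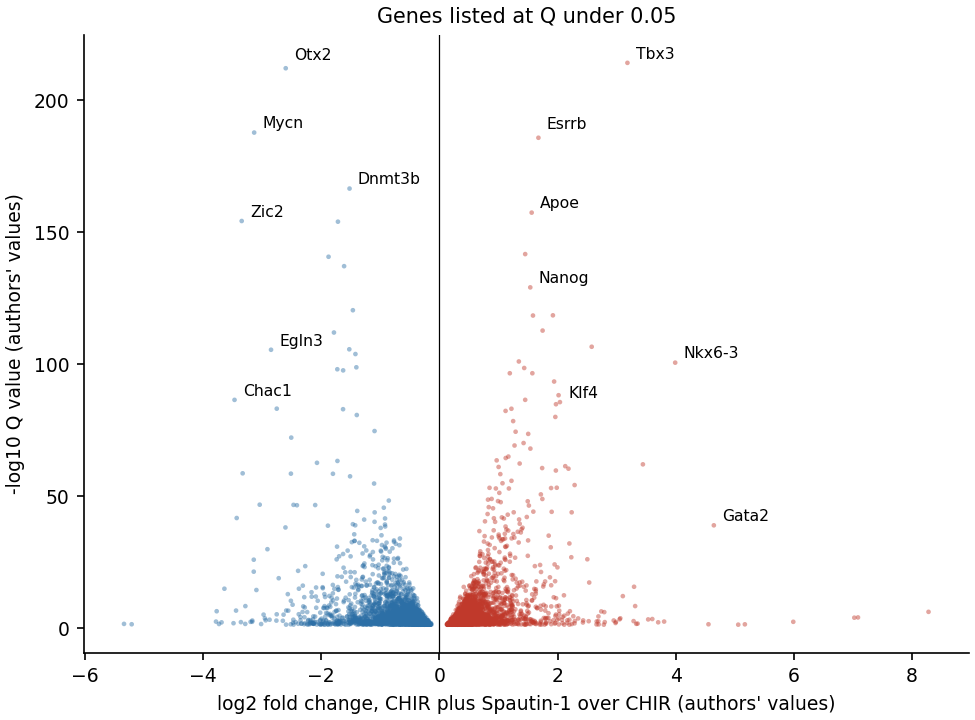
Each point is 1 of the 5021 genes in the authors' deposited table, with the log2 fold change of CHIR plus Spautin-1 over CHIR on the x axis and -log10 of the authors' Q value on the y axis. Red points are higher and blue points lower with Spautin-1. The smallest Q value belongs to Tbx3 (6.90e-215, log2 fold change 3.18), followed by Otx2 (7.62e-213, -2.60), and the points leave a gap around 0 because only genes under a Q value of 0.05 are listed.

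Of 24 naive pluripotency genes, 20 were listed in the authors' deposited table, 16 as higher and 4 as lower. Tbx3 (Entrez 21386, chromosome 5, 119670534 to 119684724), a T-box factor of the naive network, rose 9.07-fold, with a log2 fold change of 3.18 and a Q value of 6.90e-215 in the authors' deposited table. Klf4 (Entrez 16600, chromosome 4, 55527137 to 55532475) and Tfcp2l1 (Entrez 81879, chromosome 1, 118627923 to 118685168) had log2 fold changes of 2.04 and 1.75 in the authors' deposited table. Other naive factors that rose in the authors' deposited table were Prdm14 (log2 fold change 1.89), Esrrb (1.68), Nanog (1.54), Nr0b1 (1.49) and Klf2 (1.36). The 4 that fell in the authors' deposited table were Tdgf1 (-1.46), which encodes the Nodal co-receptor Cripto, Tfe3 (-0.54), Fbxo15 (-0.41) and Fgf4 (-0.18). The list was more often higher than the rest of the table by Fisher's exact test (two-sided p = 0.0134, adjusted p = 0.049 over 33 lists). That call ended when the list was compared with genes matched on GC content and length (adjusted permutation p = 0.128), and also when genes held by other lists were left out (13 of 17 higher, adjusted exact p = 0.174). The call held at a Q value under 0.01 (16 of 19 higher, adjusted exact p = 0.0251). It also held with an absolute log2 fold change of at least 1 (13 of 14 higher, adjusted exact p = 0.00262). Neither of these settings matched on GC content or length.

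Formative and primed genes went the other way, with 2 of 18 listed members higher and 16 lower in the authors' deposited table and a median log2 fold change of -1.49. This list was more often lower than the rest of the table by Fisher's exact test (p = 0.000475, adjusted p = 0.00392). Zic2 (Entrez 22772, chromosome 14, 122475384 to 122480328), a zinc finger factor of the primed epiblast, fell by 3.35 on the log2 scale in the authors' deposited table. Fgf5 (Entrez 14176, chromosome 5, 98254184 to 98277033), a marker of the post-implantation epiblast, fell by 3.14 on the log2 scale in the authors' deposited table. Otx2 (Entrez 18424, chromosome 14, 48656781 to 48667644), which drives the exit from the naive state, fell by 2.60 in the authors' deposited table, with a Q value of 7.62e-213. Sox3 (-2.64), Lef1 (-2.51), Foxd3 (-1.78), Sox4 (-1.74) and Pou3f1 (-1.73) were also lower in the authors' deposited table. So were the de novo DNA methyltransferases Dnmt3b (-1.52) and Dnmt3a (-1.41) and their cofactor Dnmt3l (-0.45), per the authors' deposited table. The 2 members that rose in the authors' deposited table were Cdh2 (1.09), which encodes N-cadherin, and Grb10 (0.67). Core pluripotency genes shared by both states were more often lower, with 3 of 11 listed members higher in the authors' deposited table, and did not pass (Fisher's exact p = 0.131, adjusted p = 0.334). Pou5f1 rose (0.45) and Sox2 fell (-0.45), both by small log2 fold changes, while L1td1 (-1.61), Dppa2 (-0.95) and Lin28a (-0.77) were lower and Tdh (0.89) was higher in the authors' deposited table. Of 21 genes of the 2-cell-like state, 1 was listed, Eif1a, at -0.38 in the authors' deposited table (Fisher's exact adjusted p = 0.75). With 1 listed gene this list could not have passed.

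Among signalling targets, feedback genes of the ERK pathway were mostly lower, 10 of 13 listed in the authors' deposited table. The farthest down in the authors' deposited table were Ier3 (log2 fold change -3.04), Myc (-2.47), Dusp6 (-2.10), Egr1 (-1.94) and Spry4 (-1.89), and Dusp4 (0.91) and Junb (0.80) were higher. This list missed the threshold by Fisher's exact test after adjustment (p = 0.049, adjusted p = 0.147) and passed it against genes matched on GC content and length (adjusted permutation p = 0.0473). Without genes held by other lists, 2 of 9 ERK feedback genes were higher, and the list did not pass (Fisher's exact adjusted p = 0.288). Of 10 listed STAT3 targets in the authors' deposited table, 8 were higher, including Gadd45g (1.79), Pim1 (1.48) and the feedback inhibitor Socs3 (1.21), and Lifr was lower (-0.53) (Fisher's exact adjusted p = 0.31). With an absolute log2 fold change of at least 1, all 6 STAT3 targets left in the authors' deposited table were higher (Fisher's exact adjusted p = 0.0334). The list did not pass against genes matched on GC content and length (adjusted permutation p = 0.669), nor without genes held by other lists, where 4 of 6 were higher in the authors' deposited table (Fisher's exact adjusted p = 0.948). BMP, Nodal and SMAD targets were mixed, 4 higher and 7 lower in the authors' deposited table, with Id2 (1.99) and Id4 (1.97) up and Id3 (-1.08), Skil (-1.63) and Pitx2 (-3.44) down (Fisher's exact adjusted p = 0.679). Of 25 Wnt and beta-catenin targets, 7 were listed in the authors' deposited table, 4 higher and 3 lower, and Axin2, the usual feedback target, was not listed (Fisher's exact adjusted p = 1). Cdx1 (3.33), Rnf43 (1.21) and Notum (0.93) were higher and Lef1 (-2.51) and Myc (-2.47) lower in the authors' deposited table, so that the median log2 fold change was 0.44 and the mean -0.02. Cdx1 and Rnf43 had Q values of 0.0227 and 0.0206. At a Q value under 0.01, 2 of 5 Wnt and beta-catenin targets were higher (Fisher's exact adjusted p = 0.965).

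All 29 listed lysosomal genes, of 36, were higher in the authors' deposited table, with a median log2 fold change of 0.77 (Fisher's exact p = 6.74e-09, adjusted p = 1.11e-07). They covered the glycosidases Hexa (1.74) and Neu1 (1.59) and the membrane proteins Cd68 (1.96), Lamp2 (1.12) and Lamp1 (0.77), with log2 fold changes from the authors' deposited table. Others were the cathepsins Ctsb (1.06) and Ctsd (0.94), the calcium channel Mcoln1 (0.64) and Tfeb (0.47), a regulator of lysosomal genes, in the authors' deposited table. The Q value of Tfeb was 0.0478, close to the threshold. Of 18 listed autophagy genes, 14 were higher and 4 lower in the authors' deposited table, and the list did not pass the threshold (Fisher's exact p = 0.0337, adjusted p = 0.111). Among them Map1lc3a (0.89), the cargo receptor Sqstm1 (0.88) and Gabarapl2 (0.79) were higher, and the mitophagy receptor Bnip3 (-1.79) and the initiation factor Rb1cc1 (-0.74) lower, in the authors' deposited table. Of 11 genes tied to the reported targets of Spautin-1, 6 were listed in the authors' deposited table, 2 higher and 4 lower (Fisher's exact adjusted p = 0.75). Usp13 rose by a log2 fold change of 0.67 with a Q value of 0.0207, Trp53 by 0.20 with a Q value of 0.00756, and Mcl1 was at -0.36, all from the authors' deposited table, while Usp10 and Becn1 were not listed.

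All 27 listed cholesterol genes, of 31, were higher in the authors' deposited table, with a median log2 fold change of 0.78 (Fisher's exact p = 2.53e-08, adjusted p = 2.78e-07). The rises in the authors' deposited table were 1.27 for Mvd, 1.13 for Cyp51, 1.00 for Hmgcr, the rate-limiting enzyme of the pathway, 0.95 for its regulator Insig1 and 0.58 for the lipoprotein receptor Ldlr. Srebf2, which encodes the transcription factor of the pathway, had a log2 fold change of 0.45, and the smallest value in the list was that of Dhcr24 (0.18), both in the authors' deposited table. The fatty acid desaturase Scd1, held by the same list, rose by 1.22 in the authors' deposited table.

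Glycolysis and hypoxia genes were lower in 22 of 28 cases listed in the authors' deposited table, with a median log2 fold change of -0.43 (Fisher's exact p = 0.00104, adjusted p = 0.00685). The deepest falls in the authors' deposited table were those of hypoxia-induced genes: the peptide hormone gene Adm (-3.28), the oxygen sensors Egln3 (-2.85) and Egln1 (-1.48), Ankrd37 (-2.31), Bnip3 (-1.79) and Ddit4 (-1.63). Glycolytic enzymes and carriers fell by less, such as Slc2a1 (-1.10), Ldha (-0.67) and Pgk1 (-0.50), and the glucose carrier Slc2a3 rose (1.03) in the authors' deposited table. With an absolute log2 fold change of at least 1, where 1 of the 10 members left in the authors' deposited table was higher, the list no longer passed (Fisher's exact adjusted p = 0.174). Nuclear genes of the respiratory chain were higher in 15 of 17 cases in the authors' deposited table by a small median log2 fold change of 0.29, with Sdhd at 0.44, Ndufv1 at 0.38 and Ndufa5 at -0.60. This list passed Fisher's exact test (p = 0.0027, adjusted p = 0.0127) and did not pass against genes matched on GC content and length (adjusted permutation p = 0.158). None of the 13 genes of the mitochondrial DNA was listed in the authors' deposited table, so that list was not tested.

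All 31 listed ribosomal protein genes, of 73, were higher in the authors' deposited table, a direction that would turn for 16 of them if every log2 fold change were 0.2 lower. Their log2 fold changes in the authors' deposited table ran from 0.13 (Rpl7) to 0.42 (Rps6), with a median of 0.20. Against the rest of the table this list passed Fisher's exact test (p = 1.8e-09, adjusted p = 5.95e-08). Chaperones and other genes of the endoplasmic reticulum stress response were higher in 14 of 16 cases in the authors' deposited table, with a median log2 fold change of 0.31 (Fisher's exact p = 0.00472, adjusted p = 0.0194). Hyou1 (0.85), Calr (0.61) and Hspa5 (0.23) were higher in the authors' deposited table, and Xbp1 (-0.63), a transcription factor of the response, and Herpud1 (-1.24) lower. The call for this list ended against genes matched on GC content and length (adjusted permutation p = 0.0924) and at a Q value under 0.01 (adjusted exact p = 0.053). Its 1 member with an absolute log2 fold change of at least 1 in the authors' deposited table, Herpud1, was lower. Of 26 listed ATF4 targets of the integrated stress response, 14 were higher and 12 lower in the authors' deposited table (Fisher's exact adjusted p = 1), with a median log2 fold change of 0.24 and a mean of -0.30. The amino acid enzyme Asns was higher (0.69), while Chac1 (-3.47), Stc2 (-1.65), Trib3 (-1.29) and Atf4 itself (-0.30) were lower in the authors' deposited table.

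Genes of the G2 and M phases were lower in 11 of 12 cases in the authors' deposited table, by a median of -0.36 on the log2 scale (Fisher's exact p = 0.00236, adjusted p = 0.0127). Cenpe (-0.85), Kif11 (-0.63), Kif23 (-0.58), the proliferation marker Mki67 (-0.37) and Cdk1 (-0.36) fell, and Ccnb2 rose (0.18), in the authors' deposited table. Against genes matched on GC content and length the adjusted permutation p was 0.0669. Genes of the G1 and S phases were mixed, 10 higher and 6 lower in the authors' deposited table, with E2f3 at -1.55 and the CDK inhibitor Cdkn1a at 0.75 (Fisher's exact adjusted p = 0.75). Of 31 histone genes, 2 were listed in the authors' deposited table, both lower, H1f0 (-1.51) and H2afz (-0.37) (Fisher's exact adjusted p = 0.47). With 2 listed genes the histone list could not have passed. p53 targets were mixed as well, with 5 higher and 4 lower in the authors' deposited table, a median log2 fold change of 0.26 and a mean of -0.07 (Fisher's exact adjusted p = 1). Pmaip1, which encodes the pro-apoptotic protein Noxa, was at -1.09 and Sesn2 at -1.39 in the authors' deposited table. Heat shock genes were higher in 5 of 8 cases in the authors' deposited table, led by Hspa1a (1.04) (Fisher's exact adjusted p = 0.945). NRF2 targets and other antioxidant genes were higher in 8 of 13, from Srxn1 (-0.87) to Gsta3 (1.28), in the authors' deposited table (Fisher's exact adjusted p = 0.854). Immediate early genes, 4 higher and 5 lower, included Btg1 (1.94) and Gadd45b (1.72) above and Egr1 and Myc below 0 in the authors' deposited table (Fisher's exact adjusted p = 0.945). For YAP and actin-related genes the counts in the authors' deposited table were 6 higher, among them Acta2 (2.74) and Acta1 (2.69), and 7 lower, among them Lats2 (-2.75) and Amotl2 (-1.27) (Fisher's exact adjusted p = 0.958).

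Markers of other cell types showed no list past the threshold. The feeder and mesoderm lists, with 1 and 2 listed genes, could not have passed Fisher's exact test whatever the direction. Of 22 markers of feeder fibroblasts, 1 was listed, Thy1, at 0.79 in the authors' deposited table (Fisher's exact adjusted p = 1). Endoderm genes were higher in 7 of 10 cases in the authors' deposited table, with Lama1 at 1.31, Fn1 at 0.82 and Dab2 at -0.98 (Fisher's exact adjusted p = 0.676). Neural genes were higher in 5 of 6 cases in the authors' deposited table, with Stmn3 at 1.76, Tubb3 at 1.11 and Nes at -0.69 (Fisher's exact adjusted p = 0.47). Of 23 genes of mesoderm and primitive streak, 2 were listed in the authors' deposited table, Snai1 (1.65) and Eomes (-1.89) (Fisher's exact adjusted p = 1). Of 18 trophectoderm genes 5 were listed in the authors' deposited table, with Tfap2c (0.97) and Krt8 (0.80) higher and Eomes among the 3 lower (Fisher's exact adjusted p = 0.927). Germline genes were higher in 5 of 6 cases in the authors' deposited table, such as Mov10l1 (1.21) and Ddx4 (0.82), with Tex19.1 at -1.14 (Fisher's exact adjusted p = 0.47). Interferon and innate immune genes were split 3 to 3 in the authors' deposited table, with Oas1a at 1.41 and Irf1 at -2.51 (Fisher's exact adjusted p = 1). Imprinted genes, 6 higher and 8 lower in the authors' deposited table, ranged from Dio3 (2.53) to Magel2 (-3.10) (Fisher's exact adjusted p = 0.854).

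**Figure D2:**
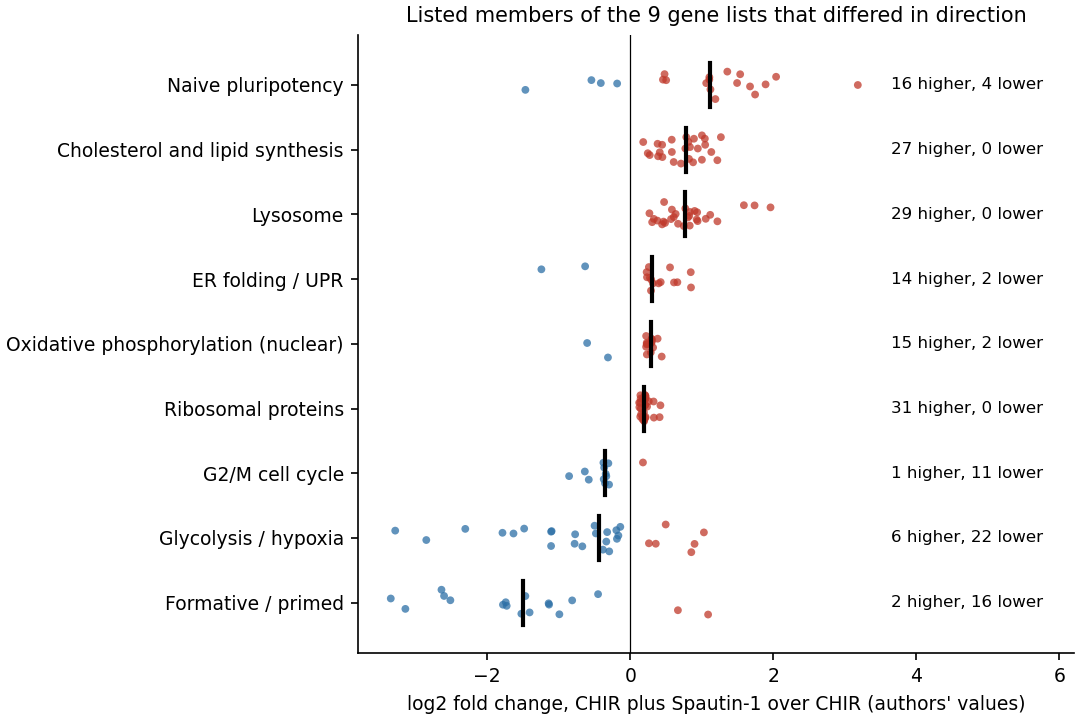
For each of the 9 lists that passed Fisher's exact test, points are the listed members' log2 fold changes of CHIR plus Spautin-1 over CHIR from the authors' deposited table, on the x axis, with a line at the list's median and the counts higher and lower beside it. All 29 lysosomal and all 27 cholesterol genes lie right of 0, as do all 31 ribosomal protein genes by at most 0.42 (15 of them if 0.2 is subtracted from every value), while 16 of 18 formative and primed genes lie left of it.

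The farthest single rises in the authors' deposited table belonged to the predicted genes Gm40368 (8.28), Gm40363 (7.08), Gm40600 (5.99) and Gm40453 (5.17) and to the homeobox gene Gsx2 (7.02), with Q values from 6.53e-07 for Gm40368 to 0.035 for Gm40453. Gata2 (Entrez 14461, chromosome 6, 88193891 to 88207032), a zinc finger factor of blood and trophoblast cells, rose by 4.64 with a Q value of 1.09e-39 in the authors' deposited table. The homeobox gene Nkx6-3 (Entrez 74561, chromosome 8, 23153271 to 23158948) rose by 3.99 with a Q value of 2.57e-101 in the authors' deposited table. Cdh17 (5.06), Grid1 (4.55), Igfbp7 (3.80), Lhx9 (3.70) and Wnt11 (3.60) complete the 12 largest rises in the authors' deposited table. The 12 largest falls in the authors' deposited table were led by the receptor genes Pth2r (-5.34, Q value 0.0238) and Ccr7 (-5.21, Q value 0.033). They went on with Ypel4 (-3.78), Stc1 (-3.77), Tal2 (-3.73), Eif3j1 (-3.69), Lpar6 (-3.64), Ppp1r3g (-3.49), Chac1 (-3.47), Pitx2 (-3.44), the chemokine gene Cxcl12 (-3.43) and St8sia2 (-3.36) in the authors' deposited table. Chac1 (Entrez 69065, chromosome 2, 119351242 to 119354326), a glutathione-degrading enzyme, had a Q value of 3.28e-87 in the authors' deposited table. Eif3j1 has a near-identical copy, Eif3j2, with which it can share reads, so its value is uncertain. Without levels, large folds with Q values near the threshold cannot be told from folds over very low counts. Among the 12 genes with the smallest Q values, chosen after the values were seen, were also Mycn (-3.14), the phosphate carrier gene Slc20a1 (1.45), Apoe (1.56), which encodes a lipid carrier, the amino acid carrier gene Slc38a2 (-1.72) and Mat2a (-1.88), which makes S-adenosylmethionine, in the authors' deposited table.

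Direction was related to the base composition of the genes. In the lowest of 10 equal classes of transcript GC content, 98 of 497 genes of the authors' deposited table were higher (19.7%, exact 95% interval 16.3 to 23.5%), against 360 of 497 in the ninth (72.4%, 68.3 to 76.3%) and 344 of 497 in the highest (69.2%, 65.0 to 73.2%). By transcript length, 64.4% of the shortest, 51.8% of the middle and 41.5% of the longest genes in the authors' deposited table were higher. Of the 9 lists called by Fisher's exact test, 5 were also called against genes of the authors' deposited table matched on both properties: formative and primed, lysosomal, cholesterol, glycolysis and hypoxia, and ribosomal protein genes. For these 5 the adjusted permutation p was 0.00132 each, from the smallest p that the 10000 draws can give. Fisher's exact test and the draws treat genes as independent, so their p-values are too small for genes that are regulated together.

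**Figure D3:**
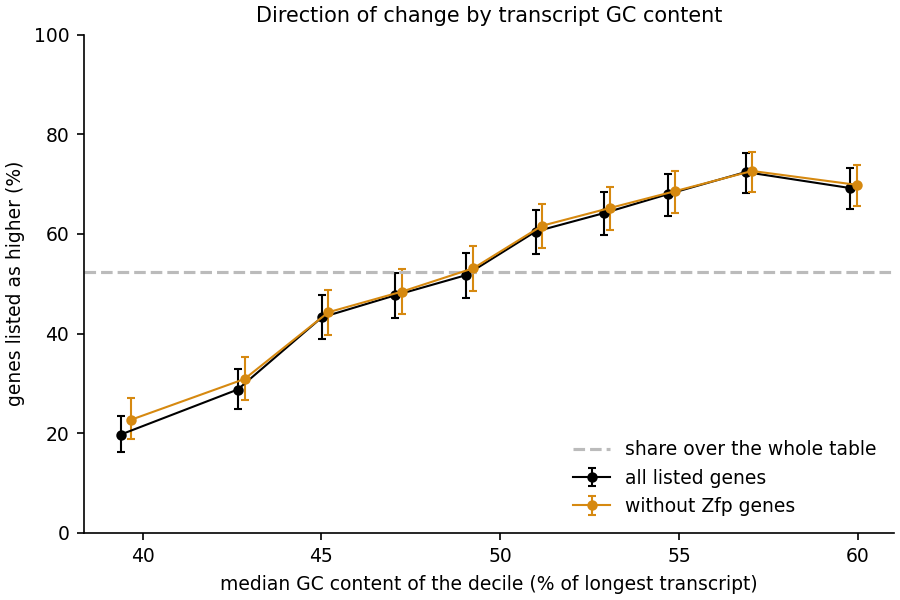
Share of genes in the authors' deposited table that were higher with Spautin-1 (y axis, percent) in 10 equal classes of GC content, placed at the class median for the longest transcript (x axis, percent). Black points are all genes and orange points, shifted slightly, leave out the zinc finger genes named Zfp. Bars are exact 95% binomial intervals and the dashed line is the 52.3% of the whole table. The black points go from 19.7% in the lowest class to 72.4% in the ninth and 69.2% in the highest, and the orange ones start at 22.7%.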

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

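The comparison with genes matched on GC content and length, the subtraction of 0.1 or 0.2 from every log2 fold change, the removal of genes held by more than 1 list and the removal of Zfp genes were chosen after the data were examined; the thresholds were set before. No paired analysis was possible because the authors' deposited table holds no values per library. For the same reason, or because it holds no group levels, no counts and only genes past the threshold, these other settings, set before, were not run: other normalizations and count tests, filters on low levels, leaving out each replicate, other pseudocounts, recomputed folds, centring on all genes and an estimated set correlation. In the authors' deposited table the count of genes went from 5021 to 3826 at a Q value under 0.01, 2789 under 0.001 and 1020 with an absolute log2 fold change of at least 1, by construction. The share higher was 52.6% at a Q value under 0.01, turned to 42.0% with an absolute log2 fold change of at least 1, and was 54.1% without Zfp genes. Of 51 alternatives for the 9 called lists, 42 kept the call, and of 141 for the other lists, 139 stayed uncalled. Both counts include the subtraction of 0.1, whose results were fixed in advance. It could not turn the direction of any gene, as the smallest absolute log2 fold change was 0.126. Ribosomal protein, respiratory chain and G2 and M phase genes had no member with an absolute log2 fold change of at least 1. That setting could not be tested for these called lists and is not among the 51. With an absolute log2 fold change of at least 1, 5 lists were called: the endoplasmic reticulum list had 1 member left and 0 higher, a reversal that rests on Herpud1 alone, glycolysis and hypoxia genes (10% higher) lost their call on fewer genes, and STAT3 targets (100% higher) gained one that no other setting gave. At a Q value under 0.01 the endoplasmic reticulum list (85.7%) lost its call. Matching on GC content and length ended the calls for naive pluripotency (80.0%), endoplasmic reticulum (87.5%), respiratory chain (88.2%) and G2 and M phase genes (8.33%), whose shares do not change by construction, and added ERK feedback genes (23.1%). Leaving out shared genes ended the call for naive pluripotency (76.5%). Subtracting 0.2 turned the share of ribosomal protein genes to 48.4%, their median being 0.20. Of the 143 genes in the authors' deposited table that the rule for named genes or the 12 smallest Q values picked, 129 passed a Q value under 0.01, 118 one under 0.001, and 95 an absolute log2 fold change of at least 1. Further genes named in the text are not in that count. Unknown depth limits what can be said of genes outside the table.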

Other observations

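The symbol families, the chromosomes, the matched draws, the small-fold comparison sets, the test of Zfp genes as the only source of the GC trend and the scaling test of lysosome and cholesterol genes were chosen after the first results were seen. Genes grouped by the stem of their symbol, 40 groups with at least 10 genes in the authors' deposited table, gave 8 with a direction different from the rest of the table at an adjusted Fisher's exact p under 0.05. Zinc finger genes named Zfp stood out: 183 of 203 in the authors' deposited table were lower with Spautin-1, with a median log2 fold change of -0.86 (Fisher's exact adjusted p = 2.19e-37). Zfp608 (-2.61), Zfp719 (-2.31) and Zfp882 (-2.28) were among the lowest, while the naive-state genes Zfp57 (1.12) and Zfp42 (0.48) were among the 20 that rose in the authors' deposited table. All 11 aldehyde dehydrogenase genes rose in the authors' deposited table, including Aldh3a1 (1.51), Aldh1l1 (1.47) and Aldh2 (0.62) (Fisher's exact adjusted p = 0.0144). So did 14 of 16 Vps genes of endosome and lysosome trafficking, such as Vps11 (0.70) and Vps37c (0.69), in the authors' deposited table (Fisher's exact adjusted p = 0.0377). Genes of the Kif family of kinesin motors fell in 10 of 11 cases (Kif21a, -1.37), those of the Trim family in 13 of 16 (Trim21, -1.54; Trim56, -1.40) and those of the Zbtb family in 13 of 16 (Zbtb4, -1.52; Zbtb20 rose by 1.16) in the authors' deposited table (Fisher's exact adjusted p = 0.0377, 0.0499 and 0.0499). The shares of the Kif and Zbtb families lay at the edge of the range of draws matched on GC content and length, at 9.09% and 18.8% higher. Rpl and Rps symbols, which overlap the ribosomal protein list, made up the other 2 groups, with 19 of 21 and 13 of 15 higher in the authors' deposited table (Fisher's exact adjusted p = 0.00559 and 0.0499). The lower genes of these 2 groups are outside that list, whose listed members all rose. Because of the overlap, the groups are no separate check of the list. By chromosome, the share higher in the authors' deposited table went from 36.6% on chromosome 13 to 63.9% on chromosome 19 (Fisher's exact adjusted p = 0.000558 and 0.0146), and no gene of the Y chromosome was listed. Without Zfp genes, of which chromosome 13 held 17 and chromosome 17 held 27, the lowest share in the authors' deposited table was 39.9% on chromosome 13 and the highest 66.5% on chromosome 17 (60.7% with them), ahead of 64.7% on chromosome 19; the role of GC content in these shares was not tested.

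The fall of Zfp genes went with a trend in GC content that covered the whole table. Base composition and length do not account for the fall in full. Of the 202 Zfp genes with a transcript, 9.90% were higher in the authors' deposited table. The median of matched draws was 39.1% (central 95% 33.2 to 45.5%), itself below the 54.1% of all other genes. Reads shared between neighbouring copies do not account for the fall in full either. Of the 46 Zfp genes with no other within 1 Mb, 19.6% were higher (exact 95% interval 9.36 to 33.9%), also below that 54.1%. Nor do Zfp genes make the GC trend, since without them 22.7% of genes in the lowest GC class were higher (exact 95% interval 18.8 to 27.0%), against 69.9% in the highest. A GC bias of the libraries cannot be told apart from a biological trend: over 31 ribosomal protein genes, log2 fold change and GC content had a Spearman's rho of 0.25 (permutation p = 0.174, bootstrap 95% interval -0.12 to 0.57), which takes in both 0 and the 0.34 of other genes with as small a fold change.

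Lysosomal and cholesterol genes rose together without exception among listed members. Base composition and length do not account for this in full. The highest 2.5% of matched draws began at 72.4% higher for the lysosomal list and 70.4% for the cholesterol list, against 100% in both. How much a scaling offset between the groups added to the rise cannot be told, as no spike-in or other reference known not to change is at hand. The share higher among all genes of the authors' deposited table (upper bound 53.7%) can be set by the normalization and by changes both ways. An offset of 0.2 would leave 100% of the lysosomal and 96.3% of the cholesterol genes higher, still more often than the rest (Fisher's exact adjusted p = 1.18e-07 and 6.69e-06). One offset would move every gene alike. The lists' median log2 fold changes of 0.77 and 0.78, against 0.20 for ribosomal protein genes, argue against an offset as the only source. The median over all listed genes (0.21) cannot be used for this, because genes near 0 are not listed. Larger offsets that made up part of the rise stay open. Whether membrane sterol was low, which would lower LXR targets while raising cholesterol synthesis, cannot be told. Of 3 LXR targets, picked after the first results were seen, 2 were listed in the authors' deposited table. Both were higher, Abca1 at 0.61 and Abcg1 at 0.36, which is not the direction low sterol would give. At least 2 of the 3 being higher had been set as the result against low sterol, and it was met. These 2 genes are still too few to decide. With 2 genes, Fisher's exact test against the rest of the table (p = 0.501) could not have passed whatever their direction. An offset of 0.2 is smaller than either rise, while a larger offset could also have raised both genes.

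Myc (-2.47) and Mycn (-3.14) fell in the authors' deposited table while all 31 listed ribosomal protein genes, whose promoters are often counted among MYC targets, rose by a median of 0.20, a direction that 15 of them would keep after a subtraction of 0.2. Base composition and length do not account in full for the ribosomal protein genes, since the highest 2.5% of matched draws began at 80.6% higher. A scaling offset of about 0.2 between the groups cannot be told apart from a rise of these genes, for the same lack of a reference. Of the other 1685 genes with as small a fold change in the authors' deposited table, 58.5% were higher (exact 95% interval 56.1 to 60.8%), but they were picked by the fold change itself and changes both ways would hide an offset, so the bound set for this test was wrong and the share decides nothing. Whether MYC-driven transcription of nucleolar genes fell cannot be told: 12 of 26 such targets were listed, 8 of them higher (66.7%, exact 95% interval 34.9 to 90.1%; Fisher's exact p = 0.393), from Tfrc (-0.60) to Mybbp1a (0.44), in the authors' deposited table.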
